A study of Mus musculus with 8 samples.

How the data were processed

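RNA was sequenced from 8 libraries of CD150-positive, CD48-negative, lineage-negative, Sca-1-positive, Kit-positive cells of mouse bone marrow, 3000 sorted cells each. Per the labels, young mice were 14 weeks old (12 per pool) and old mice 25 and 28 months (2 per pool). Cells were lysed fresh or after 26 hours in SF-O3 medium with 4% BSA, SCF at 1 ng/mL and TPO at 100 ng/mL at 1% O2. The labels call the 2 libraries of each of the 4 groups biological replicates. Which cultured library came from which pool is not given in the sources used here. RNA was taken with the RNeasy Plus Micro kit, amplified with SMART-Seq v4, sheared on a Covaris device and made into libraries with NEBNext Ultra, so the reads carry no strand.

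The deposited counts were made by the authors. The submitters' processing notes name STAR 2.7.10, featureCounts, R 4.3.0 and DESeq2 1.30.1, and the assembly mm10, without the role of each being given in the sources used here. The version of featureCounts and the handling of reads with several alignments are not given in the sources used here. The second deposited table holds signal values on a normalized scale, deposited by the authors without the tool that made it being given. Each of its libraries was tested to equal the counts divided by 1 constant, 0.920 to 1.12. It lists 22700 of 55367 symbols and leaves out 134 with a total of 11 or more counts for a reason not given.

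Libraries held 2.71e+07 to 3.51e+07 counts, a median of 434 to 534 per tested gene, with 23307 to 24982 symbols at 1 count or more, and 23937 symbols had no count in any library. Symbols of predicted genes or pseudogenes held 22.8% to 28.7% of the counts, and 53699 symbols were matched to GENCODE M21, 407 of them through older symbols. Counts of near copies (Eno1 and Eno1b, Acat2 and Acat3, Gapdh, Pgk1, Ftl1, Hmgn2) may therefore hold shared reads. Between the 2 libraries of a group, counts varied well beyond counting error (chi-square per degree of freedom of 6.41 to 15.6). The median SE of a log2 fold was 0.153 for the age effect in fresh cells and 0.216 for the difference between culture effects.

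Analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes passed filterByExpr (minimum count of 10), leaving 18613, and were scaled by TMM. A robust quasi-likelihood fit of edgeR to all 8 libraries had 1 mean per group, 4 residual degrees of freedom, a median prior of 6.13 and a biological coefficient of variation of 0.113. Contrasts were age in fresh cells, age in cultured cells, culture in young cells, culture in old cells and the difference between the 2 culture effects. Benjamini-Hochberg adjusted p under 0.05 was called a change. SE is the log2 fold over the square root of F. CPM values are edgeR's counts per unit of the TMM-scaled library total, on its preset scale.

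Gene lists, 33 in number, were written from general knowledge, and 32 with at least 5 measured genes were tested with limma camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 32. The list of Y-linked genes and Xist served only to check sex, with Xist at 0 to 2 counts and Ddx3y at 32.5 to 42.4 CPM per library. With a floor of 3 counts over a group that had none, 1 of 17 list medians with such genes moved, from 0.0590 to 0.0616 for erythroid genes.

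Comparisons, thresholds, lists and most alternatives were chosen before the data were examined. Genes named by rule were the 10 per direction with the smallest p among those with adjusted p under 0.05, a log2 fold of at least 1, separated groups and a mean of 10 CPM, predicted genes left out, and Pbx1 was always named. For the difference between culture effects, where none passed, the 5 per direction with the smallest p were given as values. From up to 4 members per list with the smallest p at a mean of 1 CPM, those printed were picked after their values were seen, partly leaving out members whose call was lost without 1 library. Gene values of single libraries for Fos, Egr1 and marker genes, 5 added lists, a fit of protein coding symbols only and a correction for transcript length and GC content were also chosen after the data were seen.

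In simulations 67, 67 and 66 of 18184 genes had log2 folds of 0.5, 1 and 2, only in old fresh cells. For age in fresh cells edgeR recovered 40.3%, 80.6% and 97.0% (11 of 156 calls false). Culture in old cells gave 31.3%, 73.1% and 90.9% (11 of 141). The difference between culture effects gave 7.46%, 52.2% and 84.8% (5 of 101, DESeq2 13 of 120). Libraries with no change gave 0 or 1 call. Camera found a list shifted by 0.4 and no other. Changes in more genes, or in correlated ones, were not tested.

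Alternatives were DESeq2 size factors, library size only, no filter on low counts, at least 5 CPM in 2 libraries, DESeq2, limma-voom, only the 4 libraries of a comparison, a spread estimate that is not robust, a replicate block of number alone or of age and number, the normalized table with a pseudocount of 1, a log2 fold of at least 1, each library left out, and for lists camera with an estimated correlation and fry. With 1 library left out, the lone library of its group was assumed to vary like the others. Reads were not realigned, since only processed tables were used.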

Results

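Haematopoietic stem cells renew the blood for life, and both aging and removal from the marrow alter which genes they transcribe. Here 8 RNA libraries held stem cells of young mice (14 weeks, pools of 12) and old mice (25 and 28 months, pools of 2), lysed fresh after the sort or after 26 hours of culture at 1% O2 with SCF at 1 ng/mL and TPO at 100 ng/mL. There were 2 libraries per group, which the labels call biological replicates, and 3000 sorted cells per library. Age was compared in fresh and in cultured cells, culture was compared in young and in old cells, and the difference between the 2 culture effects was tested as well. Culture separated the libraries along the first principal component (52.3% of the variance) and age along the second (18.98%). Pearson correlations of log2 CPM were 0.982 to 0.987 within a group and 0.941 to 0.955 between fresh and cultured libraries. CPM are means ± SD of 2 libraries, and adjusted p values are Benjamini-Hochberg values of edgeR for genes and of limma camera for gene lists, whose medians are log2 folds. For lists that shifted, counts of 0 to 2 passing members lay between 0 and 3 with 1 library left out, unless stated.

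Higher in fresh stem cells of old than of young mice were 42 of 48 genes that mark aged stem cells, 5 of 7 class II genes and 15 of 46 interferon response genes (4 without young fresh 2). Lower were 8 of 20 genes that mark multipotent progenitors (3 without old fresh 1), 8 of 44 of DNA replication and 8 of 60 of oxidative phosphorylation (0 and 0 without old fresh 1). Their lists shifted by camera with a preset correlation, and no list did with an estimated one (adjusted p = 0.224 to 0.693 for the lists that shifted). Of 18613 genes tested by edgeR, 1321 passed, 923 higher and 398 lower in old cells, and 497 of them changed at least 2-fold (415 higher, 82 lower). The count was 557, 435, 369 and 1346 without young fresh 1 and 2 and old fresh 1 and 2 in turn.

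Plscr2, which encodes a phospholipid scramblase of the cell membrane, had the smallest adjusted p, rising from 6.21 ± 0.764 CPM in young to 57.6 ± 1.09 CPM in old fresh cells (log2 fold 3.21 ± 0.12 (SE), edgeR adjusted p = 2.37e-06). Wwtr1, which encodes the Hippo pathway coactivator TAZ, was higher (log2 fold 3.57 ± 0.21 (SE), edgeR adjusted p = 7.43e-05). The retinaldehyde dehydrogenase gene Aldh1a1 averaged 81.7 ± 6.73 CPM in young and 249.9 ± 21.8 CPM in old cells (log2 fold 1.61 ± 0.10 (SE), edgeR adjusted p = 7.83e-05). Clu, which encodes a secreted chaperone, and Clec1a, which encodes a C-type lectin receptor, were both higher, at log2 folds of 2.28 (edgeR adjusted p = 9.04e-05) and 1.84 (adjusted p = 0.000116). Vwf, whose product von Willebrand factor binds platelets, rose from 112 ± 23.7 to 419 ± 37.9 CPM (log2 fold 1.90 ± 0.14 (SE), edgeR adjusted p = 0.000163). H2-Eb1, a beta chain gene of class II antigen presentation, rose from 16.2 ± 1.04 to 92.8 ± 3.77 CPM (log2 fold 2.52 ± 0.19 (SE), edgeR adjusted p = 0.000163). Also higher were the secreted Wnt modulator gene Sfrp1 (log2 fold 2.22, edgeR adjusted p = 0.000163), the endosomal trafficking gene Ehd3 (1.69, adjusted p = 0.000163) and the transcriptional coactivator gene Cited4 (2.57, adjusted p = 0.000163).

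Among genes lower in old fresh cells, Cd34, which encodes a sialomucin of progenitor surfaces, averaged 338 ± 1.98 CPM in young and 154 ± 18.1 CPM in old cells (log2 fold -1.14 ± 0.10 (SE), edgeR adjusted p = 0.000274). Flt3, the receptor gene for the FLT3 ligand on multipotent and lymphoid-primed progenitors, averaged 46.0 ± 4.47 and 16.7 ± 4.28 CPM (log2 fold -1.46 ± 0.18 (SE), edgeR adjusted p = 0.00141). Rps4l, a copy of a ribosomal protein gene, was lower (log2 fold -1.76 ± 0.15 (SE), edgeR adjusted p = 0.000285), though reads of such copies may be shared with related genes. The plexin-domain gene Plxdc2 (log2 fold -1.12, edgeR adjusted p = 0.000639) and the cytokine subunit gene Ebi3 (-1.66, adjusted p = 0.000942) were lower as well. So were the sorting nexin gene Snx20 (log2 fold -1.31, edgeR adjusted p = 0.00104) and the surface glycoprotein gene Mdga1 (-1.09, adjusted p = 0.00112). Lower too were Rassf4 (log2 fold -1.10, edgeR adjusted p = 0.00125), of the Ras association family, and the melanocortin receptor gene Mc5r (-1.02, adjusted p = 0.00147). The leukocyte transcript Lst1 was lower (log2 fold -1.28 ± 0.16 (SE), edgeR adjusted p = 0.00178).

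**Figure D1:**
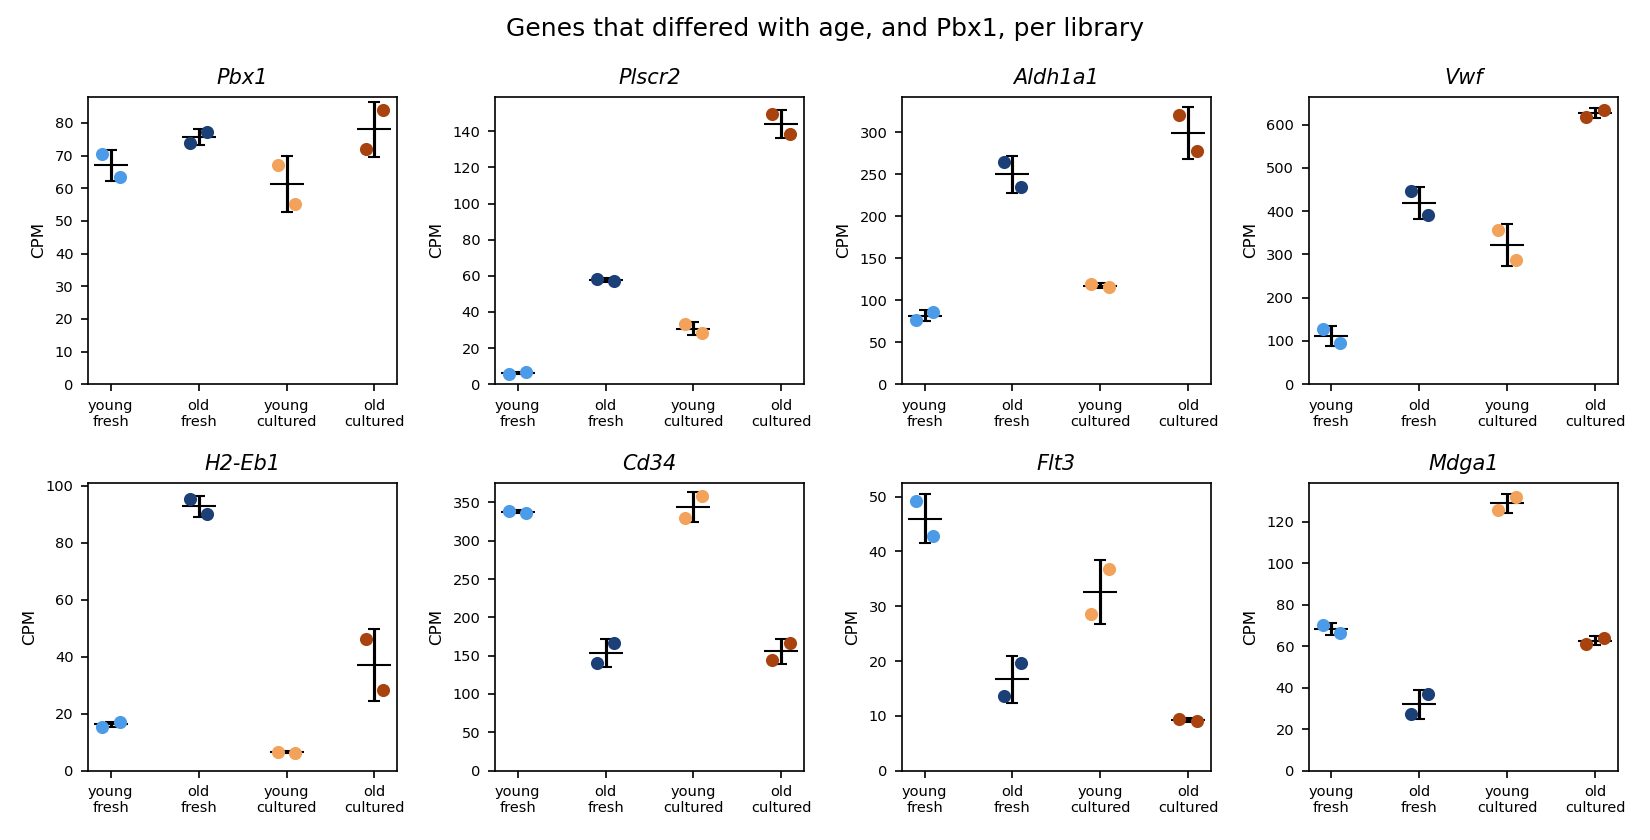
CPM of Pbx1, Plscr2, Aldh1a1, Vwf, H2-Eb1, Cd34, Flt3 and Mdga1 in the 4 groups, 1 point per library with the mean ± SD of 2 libraries. Plscr2 averaged 6.21 CPM in young and 57.6 CPM in old fresh cells, and Pbx1 lay between 61.2 and 78.0 CPM on average.

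Pbx1, which encodes a homeodomain partner of the HOX and MEIS proteins, lies on chromosome 1 (168119364 to 168432270, minus strand). It averaged 67.0 ± 4.86 CPM in young and 75.6 ± 2.40 CPM in old fresh cells, and did not pass (log2 fold 0.17 ± 0.11 (SE), edgeR adjusted p = 0.398). In the list of PBX, MEIS and HOX genes, 3 of 23 genes passed as higher and 0 as lower (20 did not), 5 and 1 adjusted over the list alone. The median was 0.13 (camera adjusted p = 0.0424). The paralog Pbx3 (log2 fold 1.34, edgeR adjusted p = 0.00154) and Meis3 (1.38, adjusted p = 0.00368) were higher. The shift of this list was lost with single libraries left out (adjusted p = 0.0811, 0.0533 and 0.0605 without young fresh 2 and old fresh 1 and 2 in turn). The median became 0.25 and 0.22 without young fresh 1 and old fresh 1 in turn.

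A list of genes known to be higher in aged stem cells covers adhesion, clotting and signaling. Of it, 42 of 48 genes passed as higher and 0 as lower (6 did not), 44 and 1 adjusted over the list alone. Median 1.83 was accompanied by camera adjusted p = 5.01e-44. Selp, the P-selectin gene, was higher (log2 fold 3.52 ± 0.26 (SE), edgeR adjusted p = 0.000337), and so was Neo1, a netrin receptor gene (log2 fold 2.55 ± 0.23 (SE), adjusted p = 0.000330). The megakaryocyte and platelet list shifted upward, where 7 of 28 genes passed as higher and 0 as lower (21 did not), 12 and 0 adjusted over the list alone. Its median of 0.47 came with camera adjusted p = 1.06e-08. The median became 0.20 without old fresh 2. Its higher members numbered 4 and 4 without young fresh 1 and 2 in turn. Cavin2, a caveolae gene, and Mmrn1, which encodes multimerin, were among them, at log2 folds of 1.50 (edgeR adjusted p = 0.000337) and 0.71 (adjusted p = 0.000917). The 2 lists share 5 genes including Vwf and Selp, and without the shared genes 3 of 23 megakaryocyte genes passed as higher, with a median log2 fold of 0.38.

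On the stem cell surface list, 8 of 25 genes passed as higher and 1 as lower (16 did not), 12 and 3 adjusted over the list alone. The median was 0.25 (camera adjusted p = 1.15e-05). Itga6, the integrin alpha 6 gene, was higher (log2 fold 0.87 ± 0.08 (SE), edgeR adjusted p = 0.000371), while Slamf1, also higher (log2 fold 0.84 ± 0.11 (SE), adjusted p = 0.00166), encodes CD150, by which the cells were sorted, and is no finding. The higher surface members numbered 5, 4 and 4 without young fresh 1 and 2 and old fresh 1 in turn. The median became 0.37 without old fresh 2. On the stem cell transcription factor list, 7 of 33 genes passed as higher and 0 as lower (26 did not), 11 and 1 adjusted over the list alone. Median 0.11 was accompanied by camera adjusted p = 0.00400. Mycn, which encodes a MYC family factor, passed as higher (log2 fold 0.90 ± 0.11 (SE), edgeR adjusted p = 0.00141). The higher transcription factors numbered 2, 1 and 1 without young fresh 1 and 2 and old fresh 1 in turn. The median became 0.17, 0.18 and 0.20 without young fresh 1 and 2 and old fresh 2 in turn.

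Genes of multipotent progenitors moved the other way, as 1 of 20 genes passed as higher and 8 as lower (11 did not), 2 and 9 adjusted over the list alone. Its median of -0.47 came with camera adjusted p = 1.15e-05. They include Cd34 and Flt3, and Cd48 (log2 fold -2.70, edgeR adjusted p = 0.00177), whose product CD48 was itself sorted against and is no finding. The counts, median and camera value of the list still hold Cd48. The lower members numbered 5, 4 and 3 without young fresh 1 and 2 and old fresh 1 in turn. Interferon response genes were shifted upward, in that 15 of 46 genes passed as higher and 0 as lower (31 did not), 22 and 1 adjusted over the list alone. The median was 0.39 (camera adjusted p = 1.52e-08). Among them were Stat1, a transcription factor of interferon signaling (log2 fold 0.96 ± 0.12 (SE), edgeR adjusted p = 0.00159), and the interferon-inducible GTPase genes Igtp (log2 fold 0.95, adjusted p = 0.00144) and Ifi47 (0.48, adjusted p = 0.00304). The count of higher interferon genes was 7, 4, 7 and 7 without young fresh 1 and 2 and old fresh 1 and 2 in turn. In the antigen presentation list, 10 of 24 genes passed as higher and 0 as lower (14 did not), 15 and 1 adjusted over the list alone, with H2-Ab1 (log2 fold 1.55, edgeR adjusted p = 0.000351), H2-Aa (1.87, adjusted p = 0.000597) and their activator Ciita (2.03, adjusted p = 0.00119) among the higher. Median 0.32 was accompanied by camera adjusted p = 1.03e-07. The higher members of that list numbered 5, 5 and 4 without young fresh 1 and 2 and old fresh 1 in turn.

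For oxidative phosphorylation, 0 of 60 genes passed as higher and 8 as lower (52 did not), 0 and 25 adjusted over the list alone. Its median of -0.23 came with camera adjusted p = 4.82e-12. Ndufa4, a subunit gene of the respiratory chain, was lower (log2 fold -0.51 ± 0.08 (SE), edgeR adjusted p = 0.00679, adjusted p = 0.0599 without old fresh 1). The lower members numbered 2, 1, 4, 4 and 0 without young fresh 1 and 2, young cultured 1 and 2 and old fresh 1 in turn. For DNA replication, 0 of 44 genes passed as higher and 8 as lower (36 did not), 0 and 17 adjusted over the list alone. The median was -0.25 (camera adjusted p = 2.40e-09). The sliding clamp gene Pcna (log2 fold -0.34, edgeR adjusted p = 0.0204) was lower, but lost its call with single libraries left out (adjusted p = 0.145, 0.104 and 0.0655 without young fresh 1 and old fresh 1 and 2 in turn). The lower replication genes numbered 0, 1, 4, 4 and 0 without young fresh 1 and 2, young cultured 1 and 2 and old fresh 1 in turn. The median became -0.15 without old fresh 1. For mitosis, 0 of 38 genes passed as higher and 3 as lower (35 did not), 0 and 6 adjusted over the list alone. Median -0.20 was accompanied by camera adjusted p = 8.76e-06. For mitosis the median became -0.34, -0.09 and -0.31 without young fresh 1 and 2 and old fresh 2 in turn. Its lower members numbered 1, 0, 0, 6 and 6 without young fresh 1 and 2, old fresh 1 and old cultured 1 and 2 in turn. For cholesterol synthesis, 0 of 24 genes passed as higher and 4 as lower (20 did not), 1 and 8 adjusted over the list alone, among them the isoprenoid gene Idi1 (log2 fold -0.59, edgeR adjusted p = 0.00249). Its median of -0.16 came with camera adjusted p = 0.000494. Lower members numbered 1 and 1 without young fresh 1 and old fresh 1 in turn. For the cytoplasmic ribosome, 0 of 74 genes passed as higher and 0 as lower (74 did not), 0 and 0 adjusted over the list alone. The median was -0.16 (camera adjusted p = 7.74e-10). The median became -0.10 without young fresh 1.

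Cytokine target genes of the JAK-STAT pathway shifted upward, where 6 of 31 genes passed as higher and 1 as lower (24 did not), 8 and 3 adjusted over the list alone. Median 0.17 was accompanied by camera adjusted p = 0.00400. The feedback inhibitor gene Socs3 (log2 fold 2.36, edgeR adjusted p = 0.000908) and the transcription factor gene Stat3 (0.58, adjusted p = 0.00198) were higher. The shift was lost in 1 case (adjusted p = 0.0984 without old fresh 2). Among immediate early genes, 2 of 32 genes passed as higher and 2 as lower (28 did not), 2 and 3 adjusted over the list alone. Its median of -0.47 came with camera adjusted p = 0.0424. This list rested on 1 library, since Fos stood at 694 CPM and Egr1 at 489.8 CPM in young fresh 2 but at 79.4 and 91.4 CPM in young fresh 1, and 30 of the 32 genes were higher there (median log2 difference 1.14). Its shift was lost in 4 cases (adjusted p = 0.949, 0.143, 0.0663 and 0.0665 without young fresh 2, old fresh 1 and old cultured 1 and 2 in turn). The median became -1.05, 0.14, -0.39 and -0.78 without young fresh 1 and 2 and old fresh 1 and 2. In the endothelium and stroma list, 3 of 16 genes passed as higher and 0 as lower (13 did not), 3 and 1 adjusted over the list alone, a shift also lost (adjusted p = 0.0570 and 0.198 without young fresh 2 and old fresh 1 in turn, median 0.37 to 0.75 with 1 library left out). The median was 0.43 (camera adjusted p = 0.0414). Its higher members numbered 0, 1 and 0 without young fresh 1 and 2 and old fresh 1 in turn.

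The other lists did not shift between old and young fresh cells with all 8 libraries. Of the signaling and metabolic lists these were glycolysis (4 higher, 0 lower of 25, camera adjusted p = 0.0891), p53 targets (4 higher, 0 lower of 27, camera adjusted p = 0.0661), hypoxia (0 higher, 2 lower of 32, camera adjusted p = 0.549) and the ATF4 amino acid response (4 higher, 2 lower of 34, camera adjusted p = 0.250). Further such lists were the unfolded protein response (3 higher, 1 lower of 29, camera adjusted p = 0.250), NF-kB inflammation (3 higher, 1 lower of 27, camera adjusted p = 0.549), lysosomes and autophagy (2 higher, 0 lower of 35, camera adjusted p = 0.113) and CDK inhibitors and quiescence (3 higher, 0 lower of 27, camera adjusted p = 0.452). Of the remaining lists these were ribosome biogenesis (0 higher, 0 lower of 50, camera adjusted p = 0.510), the mitochondrial genome (0 higher, 0 lower of 13, camera adjusted p = 0.250), adhesion and cytoskeleton (9 higher, 4 lower of 40, camera adjusted p = 0.0963) and erythroid cells (2 higher, 0 lower of 23, camera adjusted p = 0.216). The rest were granulocytes and monocytes (1 higher, 0 lower of 26, camera adjusted p = 0.452), lymphoid progenitors and B cells (0 higher, 2 lower of 17, camera adjusted p = 0.0565), T and NK cells (2 higher, 2 lower of 10, camera adjusted p = 0.461) and mast cells and basophils (2 higher, 0 lower of 8, camera adjusted p = 0.191). With 1 library left out, p53 targets shifted up without young fresh 2 and old cultured 1 and 2 (adjusted p = 0.0384, 0.0349 and 0.0371), the lymphoid list down without young fresh 2 and young cultured 1 and 2 (adjusted p = 0.00504, 0.0475 and 0.0458) and lysosomes up without old fresh 2 (adjusted p = 0.0241). The mitochondrial genome shifted up without young fresh 1 (adjusted p = 0.00108, median 0.28) and down without young fresh 2 (adjusted p = 9.16e-09, median -0.44), granulocytes up without young fresh 1 (adjusted p = 0.000785, median 1.09) and erythroid cells up without old fresh 1 (adjusted p = 7.02e-08, median 0.61) and down without old fresh 2 (adjusted p = 0.0495, median -0.59). In all, 16 of 32 lists shifted by camera with a preset correlation (9 up, 7 down), 0 with the estimated correlation and 5 by fry. With 2 pools of mice per age, an age effect could not be parted from other differences between those pools.

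After 26 hours in culture, stem cells of old and young mice still differed, with genes of the aged stem cell list and of multipotent progenitors among those that passed. Of 18613 genes tested by edgeR, 389 passed, 186 higher and 203 lower, and 195 changed at least 2-fold. The count was 107 and 39 without young cultured 1 and young cultured 2 in turn.

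Plscr2 rose with age from 30.8 ± 3.61 to 144 ± 7.73 CPM (log2 fold 2.23 ± 0.11 (SE), edgeR adjusted p = 2.69e-05). Of the genes named for fresh cells, Aldh1a1 (log2 fold 1.35, edgeR adjusted p = 0.000591), H2-Eb1 (2.53, adjusted p = 0.000819) and Clu (1.58, adjusted p = 0.000950) were also higher in old cultured cells. The same held for Wwtr1 (log2 fold 2.02, edgeR adjusted p = 0.00101) and Clec1a (1.37, adjusted p = 0.00106). It held as well for Cited4 (log2 fold 1.93, edgeR adjusted p = 0.00156) and Sfrp1 (1.51, adjusted p = 0.00353). H2-Aa, the class II alpha chain gene, was higher (log2 fold 2.12 ± 0.21 (SE), edgeR adjusted p = 0.00153), and so was Ccnd1, which encodes cyclin D1 (log2 fold 1.48 ± 0.17 (SE), adjusted p = 0.00353). Lower were Rps4l (log2 fold -2.03, edgeR adjusted p = 0.000732), Cd34 (-1.15, adjusted p = 0.000950) and Flt3 (-1.82, adjusted p = 0.00159). The surface peptidase gene Dpp4 (log2 fold -1.29, edgeR adjusted p = 0.00101) and Snx20 (-1.48, adjusted p = 0.00153) were lower too. The anthrax toxin receptor gene Antxr2 (log2 fold -1.01, edgeR adjusted p = 0.00369), the collagen gene Col4a2 (-1.17, adjusted p = 0.00369) and the cholesterol exporter gene Abca1 (-1.18, adjusted p = 0.00588) followed. Mdga1 and Rassf4 were lower at log2 folds of -1.04 (edgeR adjusted p = 0.00369) and -1.03 (adjusted p = 0.00492). Without young cultured 2, Ccnd1, Mdga1, Antxr2, Col4a2, Rassf4 and Abca1 lost their calls, at edgeR adjusted p values of 0.0637, 0.0579, 0.0616, 0.0579, 0.0760 and 0.0848 in that order.

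Pbx1 averaged 61.2 ± 8.56 CPM in young and 78.0 ± 8.41 CPM in old cultured cells and did not pass (log2 fold 0.35 ± 0.11 (SE), edgeR adjusted p = 0.183), although it did with no filter on low counts (adjusted p = 0.0275). In the PBX, MEIS and HOX list, 1 of 23 genes passed as higher and 0 as lower (22 did not), 3 and 0 adjusted over the list alone. Median 0.18 was accompanied by camera adjusted p = 0.0269. Pbx3 was the higher one (log2 fold 1.16 ± 0.17 (SE), edgeR adjusted p = 0.00777, adjusted p = 0.0581 and 0.109 without young cultured 1 and 2 in turn). The shift of the list was lost with single libraries left out (adjusted p = 0.0785 and 0.260 without young cultured 1 and old cultured 1 in turn, median 0.09 to 0.24 with 1 library left out).

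With an estimated correlation no list shifted with age in cultured cells (camera adjusted p of 0.124 to 0.927 for the lists that did with the preset one). Of the aged stem cell list, 31 of 48 genes passed as higher and 0 as lower (17 did not), 39 and 0 adjusted over the list alone. Its median of 1.12 came with camera adjusted p = 4.81e-45. Ramp2, a receptor-modifying gene, and Selp were among the higher, at log2 folds of 3.11 (edgeR adjusted p = 0.00101) and 2.47 (adjusted p = 0.00369). The higher members numbered 14 and 6 without young cultured 1 and 2 in turn, while the list shifted in each case. Of the progenitor list, 0 of 20 genes passed as higher and 6 as lower (14 did not), 0 and 12 adjusted over the list alone. Cd48 (log2 fold -2.25, edgeR adjusted p = 0.00505) is counted among the lower, but as a sort marker is again no finding. Its call was lost without young cultured 2 (log2 fold -2.17). The median was -0.56 (camera adjusted p = 2.32e-11). The lower progenitor genes numbered 3 and 2 without young cultured 1 and 2 in turn. Of the lymphoid list, 0 of 17 genes passed as higher and 2 as lower (15 did not), 0 and 2 adjusted over the list alone. Median -0.63 was accompanied by camera adjusted p = 0.000151.

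In the megakaryocyte list, 4 of 28 genes passed as higher and 1 as lower (23 did not), 8 and 1 adjusted over the list alone (1 and 1 of 23 passed without the 5 genes shared with the aged list), with Vwf (log2 fold 0.96 ± 0.14 (SE), edgeR adjusted p = 0.00770, adjusted p = 0.101 without young cultured 2) higher. Its median of 0.34 came with camera adjusted p = 0.000189. The shift was lost in 1 case (adjusted p = 0.689 without old cultured 2). The median became 0.20, 0.65 and -0.05 without young cultured 2 and old cultured 1 and 2 in turn, and the higher members numbered 1 without young cultured 2. In the antigen presentation list, 2 of 24 genes passed as higher and 0 as lower (22 did not), 3 and 0 adjusted over the list alone, a shift lost as well (adjusted p = 0.451 without old cultured 1). The median was 0.09 (camera adjusted p = 0.00105). The median became 0.15, -0.03 and 0.23 without young cultured 2 and old cultured 1 and 2 in turn, and 5 members were higher without old cultured 2. Oxidative phosphorylation moved upward, where 0 of 60 genes passed as higher and 0 as lower (60 did not), 0 and 0 adjusted over the list alone. Median 0.07 was accompanied by camera adjusted p = 0.000223. The median became 0.12 without young cultured 1. The ribosome list gave 0 higher and 0 lower genes of 74 (median 0.08, camera adjusted p = 0.000633), lost with single libraries left out (adjusted p = 0.410 and 0.605 without young cultured 2 and old cultured 1 in turn, median 0.01 to 0.13 with 1 library left out). Ribosome biogenesis gave 0 higher and 0 lower of 50 (median 0.10, camera adjusted p = 0.000371), a shift with adjusted p = 0.980 without old cultured 2 (median -0.00 to 0.18 with 1 library left out).

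For the list of heat shock and unfolded protein genes, 0 of 29 genes passed as higher and 1 as lower (28 did not), 0 and 1 adjusted over the list alone, so that its median was positive while its single passing gene was lower. Its median of 0.20 came with camera adjusted p = 0.00285. That shift was lost without 1 library (adjusted p = 0.688 without old cultured 2, median 0.05 without old cultured 2), and 5 members were higher without old cultured 1. For NF-kB inflammation, 0 of 27 genes passed as higher and 2 as lower (25 did not), 1 and 3 adjusted over the list alone, with the shift lost in 2 cases (adjusted p = 0.423 and 0.689 without young cultured 1 and old cultured 2 in turn). The median was -0.34 (camera adjusted p = 0.0336). The median became -0.15, -0.67 and -0.13 without young cultured 1 and old cultured 1 and 2 in turn. For lysosomes and autophagy, 0 of 35 genes passed as higher and 2 as lower (33 did not), 0 and 3 adjusted over the list alone, with the shift lost in 1 case (adjusted p = 0.316 without old cultured 2, median -0.14 to -0.04 with 1 library left out). Median -0.06 was accompanied by camera adjusted p = 0.00120. The interferon list did not shift in cultured cells, with 2 higher and 0 lower of 46 (median log2 fold 0.03, camera adjusted p = 0.548), but it shifted up without young cultured 2 and old cultured 2 (adjusted p = 0.0305 and 0.00935, median 0.11 and 0.15). In total 12 of 32 lists shifted (8 up, 4 down) by camera with a preset correlation and 2 by fry.

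Between the age effects in fresh and in cultured cells, which share no libraries, 157 genes were higher in both (9.22 expected if independent) and 64 lower in both (4.34 expected), and 0 passed in opposite directions by edgeR. Whether fresh and cultured cells shared pools of mice is not given in the sources used here, and shared pools could raise the number expected. The shared count was 77 and 30 without young cultured 1 and young cultured 2 in turn. Over the 18613 genes tested, the log2 folds of age correlated with r = 0.386 (Pearson) and 0.145 (Spearman).

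**Figure D2:**
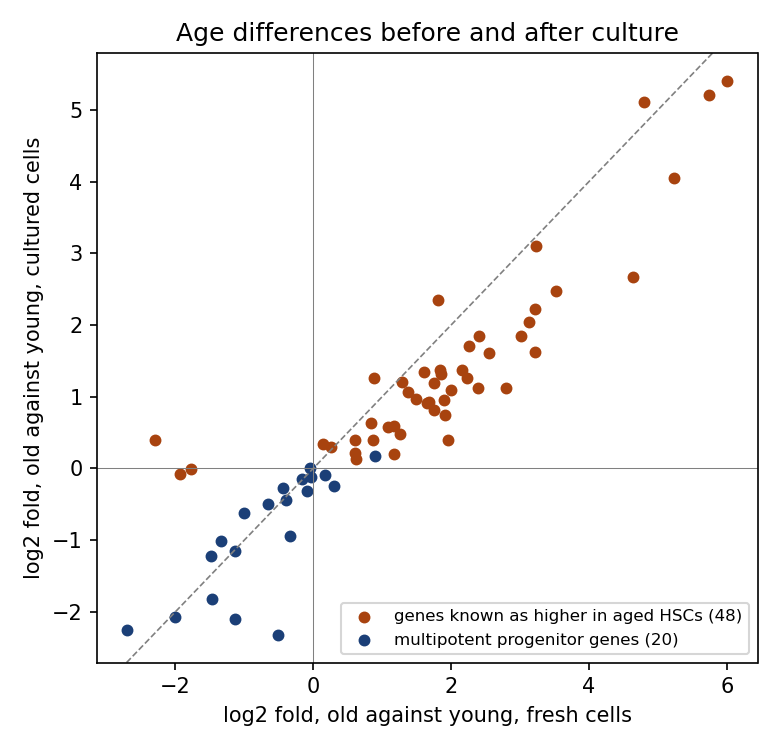
Log2 fold of old against young cells in fresh (horizontal) and cultured (vertical) cells for 48 genes of the aged stem cell list and 20 of the multipotent progenitor list, 1 point per gene. The aged list has medians of 1.83 in fresh and 1.12 in cultured cells, and the progenitor list has -0.47 and -0.56.

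Culture for 26 hours raised transcripts of cholesterol synthesis in young stem cells, the 1 list of 32 to shift with an estimated correlation too (camera adjusted p = 0.00746). By edgeR 6004 of 18613 genes passed, 3102 up and 2902 down, and 1784 of them changed at least 2-fold. Directions depend on the scaling, as the median log2 fold of all genes was -0.18 in young and -0.16 in old cells with library size only. Of the genes that then passed, 28.8% were up in young cells and 27.4% in old cells, against 51.7% and 48.2% with TMM factors. Changes are given relative to TMM scaling, and of the genes named below only Pbx1 in old cells, not called, turned direction with library size only, from 0.05 to -0.11. The count in young cells was 3955, 3683 and 3564 without young fresh 1, young cultured 1 and young cultured 2 in turn.

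Idi1, which encodes an isomerase of isoprenoid units, rose from 70.8 ± 1.63 to 584 ± 9.29 CPM (log2 fold 3.04 ± 0.08 (SE), edgeR adjusted p = 1.17e-08). Other genes of the sterol pathway rose with it, namely Hmgcs1 (log2 fold 3.25, edgeR adjusted p = 1.72e-08), Fdft1 (3.02, adjusted p = 1.75e-08) and Cyp51 (3.03, adjusted p = 2.12e-08). So did Msmo1 (log2 fold 3.02, edgeR adjusted p = 2.12e-08) and Acat2 (2.40, adjusted p = 9.78e-09). Scd1, a fatty acid desaturase gene, rose (log2 fold 3.48 ± 0.09 (SE), edgeR adjusted p = 9.78e-09), as did Gclm, a subunit gene of the enzyme that begins glutathione synthesis (log2 fold 2.62 ± 0.07 (SE), adjusted p = 9.78e-09). Eno1, an enolase gene of glycolysis, rose (log2 fold 2.40 ± 0.06 (SE), edgeR adjusted p = 9.78e-09), and its near copy Eno1b (log2 fold 2.40, adjusted p = 9.78e-09) held 75.8% as many counts, so reads of the 2 may be shared. Dusp6, which encodes a phosphatase of ERK, fell from 58.6 ± 1.78 to 6.79 ± 0.356 CPM (log2 fold -3.11 ± 0.12 (SE), edgeR adjusted p = 4.89e-08). The mitochondrial DNA polymerase gene Polg (log2 fold -2.31, edgeR adjusted p = 2.14e-07) and the nucleosome binding gene Hmgn2 (-1.08, adjusted p = 9.74e-07) fell. The transferrin receptor gene Tfr2 (log2 fold -1.32, edgeR adjusted p = 2.43e-06) and the cytokinesis gene Ect2 (-2.87, adjusted p = 4.71e-06) fell as well. Falls were also seen in the TNF receptor gene Tnfrsf18 (log2 fold -2.11, edgeR adjusted p = 4.87e-06) and the kinase genes Prkd2 (-1.13, adjusted p = 7.66e-06) and Camkk1 (-1.91, adjusted p = 8.73e-06). The last of the falls were in the kinase activator gene Mob3c (log2 fold -2.27, edgeR adjusted p = 8.53e-06) and the selenoprotein gene Selenoh (-1.44, adjusted p = 1.03e-05). Pbx1 did not pass (log2 fold -0.13 ± 0.11 (SE), edgeR adjusted p = 0.414).

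All sterol pathway genes rose, since for cholesterol synthesis 24 of 24 genes passed as up and 0 as down (0 did not), 24 and 0 adjusted over the list alone. Its median of 2.57 came with camera adjusted p = 5.05e-28 and adjusted p = 0.00746 with an estimated correlation. For glycolysis 20 of 25 genes passed as up and 0 as down (5 did not), 20 and 0 adjusted over the list alone, including the aldolase gene Aldoa (log2 fold 2.13, edgeR adjusted p = 2.35e-08) and the kinase gene Pgk1 (1.95, adjusted p = 2.47e-08). The median was 1.28 (camera adjusted p = 5.97e-17 and adjusted p = 0.113 with an estimated correlation). For hypoxia 19 of 32 genes passed as up and 0 as down (13 did not), 20 and 0 adjusted over the list alone, including the mitophagy gene Bnip3 (log2 fold 2.12, edgeR adjusted p = 5.47e-07) and the angiogenic factor gene Vegfa (2.66, adjusted p = 2.22e-06). Median 0.80 was accompanied by camera adjusted p = 8.23e-10 and adjusted p = 0.191 with an estimated correlation. For the ATF4 amino acid response 25 of 34 genes passed as up and 1 as down (8 did not), 25 and 1 adjusted over the list alone, including the asparagine synthetase gene Asns (log2 fold 1.82, edgeR adjusted p = 9.61e-07) and the glycine transporter gene Slc6a9 (3.36, adjusted p = 1.59e-06). Its median of 0.95 came with camera adjusted p = 2.66e-12 and adjusted p = 0.0616 with an estimated correlation. For p53 targets 16 of 27 genes passed as up and 2 as down (9 did not), 16 and 2 adjusted over the list alone. The median was 0.84 (camera adjusted p = 1.24e-05 and adjusted p = 0.583 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 4.60 ± 0.171 to 115 ± 8.38 CPM (log2 fold 4.64 ± 0.22 (SE), edgeR adjusted p = 2.75e-07), and the death effector gene Bax (log2 fold 2.10, adjusted p = 9.19e-07) rose. For megakaryocytes and platelets 17 of 28 genes passed as up and 0 as down (11 did not), 19 and 0 adjusted over the list alone, including the tetraspanin gene Cd9 (log2 fold 1.31, edgeR adjusted p = 3.92e-06). Median 0.92 was accompanied by camera adjusted p = 6.28e-07 and adjusted p = 0.636 with an estimated correlation. Members up numbered 9, 8 and 10 without young fresh 1 and 2 and young cultured 1 in turn.

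For the interferon response 1 of 46 genes passed as up and 21 as down (24 did not), 2 and 24 adjusted over the list alone, with the GTPase gene Ifi47 (log2 fold -0.79, edgeR adjusted p = 1.84e-05) down. Its median of -0.47 came with camera adjusted p = 2.95e-06 and adjusted p = 0.636 with an estimated correlation. For antigen presentation 2 of 24 genes passed as up and 10 as down (12 did not), 2 and 14 adjusted over the list alone, with H2-Aa (log2 fold -2.08, edgeR adjusted p = 5.75e-05) and the light chain gene B2m (-0.49, adjusted p = 0.000782) down. The median was -0.27 (camera adjusted p = 0.000443 and adjusted p = 0.658 with an estimated correlation). Members down numbered 6 without young cultured 1. For the cytoplasmic ribosome 2 of 74 genes passed as up and 45 as down (27 did not), 2 and 50 adjusted over the list alone, with the stalk protein gene Rplp1 (log2 fold -0.81, edgeR adjusted p = 5.33e-05) down. Median -0.29 was accompanied by camera adjusted p = 6.37e-10 and adjusted p = 0.658 with an estimated correlation. The ribosomal genes down numbered 20 and 19 without young fresh 1 and young cultured 2 in turn. For oxidative phosphorylation 0 of 60 genes passed as up and 22 as down (38 did not), 0 and 22 adjusted over the list alone, with Ndufv1 (log2 fold -0.56, edgeR adjusted p = 0.000512) down. Its median of -0.20 came with camera adjusted p = 1.06e-06 and adjusted p = 0.636 with an estimated correlation. Members down numbered 6, 14, 8 and 4 without young fresh 1 and 2 and young cultured 1 and 2 in turn. For the PBX, MEIS and HOX list 1 of 23 genes passed as up and 6 as down (16 did not), 1 and 6 adjusted over the list alone, with the homeobox gene Hoxa9 (log2 fold -1.22, edgeR adjusted p = 9.12e-05) down. The median was -0.50 (camera adjusted p = 0.00421 and adjusted p = 0.283 with an estimated correlation). Members down numbered 2 and 3 without young fresh 2 and young cultured 1 in turn. For DNA replication 2 of 44 genes passed as up and 16 as down (26 did not), 3 and 20 adjusted over the list alone, with the helicase gene Mcm7 (log2 fold -0.57, edgeR adjusted p = 0.000247) down. Median -0.24 was accompanied by camera adjusted p = 0.000560 and adjusted p = 0.667 with an estimated correlation. The replication genes down numbered 8 without young cultured 2.

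For mitosis 1 of 38 genes passed as up and 9 as down (28 did not), 1 and 9 adjusted over the list alone, a shift lost with single libraries left out (adjusted p = 0.144 and 0.0799 without young fresh 2 and young cultured 2 in turn, median -0.37 to -0.13 with 1 library left out). Its median of -0.27 came with camera adjusted p = 0.00468 and adjusted p = 0.695 with an estimated correlation. Its members down numbered 2 and 2 without young fresh 2 and young cultured 2 in turn. For lysosomes and autophagy 16 of 35 genes passed as up and 2 as down (17 did not), 18 and 2 adjusted over the list alone, with the protease gene Ctsd (log2 fold 1.58, edgeR adjusted p = 1.44e-06) up. The median was 0.28 (camera adjusted p = 0.000864 and adjusted p = 0.658 with an estimated correlation). Members up numbered 10 and 8 without young fresh 2 and young cultured 1 in turn. For ribosome biogenesis 18 of 50 genes passed as up and 1 as down (31 did not), 18 and 1 adjusted over the list alone, with the nucleolar gene Npm1 (log2 fold 0.47, edgeR adjusted p = 0.000781) up. Median 0.12 was accompanied by camera adjusted p = 0.00567 and adjusted p = 0.695 with an estimated correlation. The median of that list was -0.06 when only library size was used, and its members up numbered 8, 11, 10 and 9 without young fresh 1 and 2 and young cultured 1 and 2 in turn. For granulocytes and monocytes 3 of 26 genes passed as up and 5 as down (18 did not), 3 and 5 adjusted over the list alone, with the receptor gene Csf3r (log2 fold -1.15, edgeR adjusted p = 0.00102) down. Its median of -1.33 came with camera adjusted p = 0.0256 and adjusted p = 0.695 with an estimated correlation. That shift was lost too (adjusted p = 0.456 and 0.187 without young fresh 1 and young cultured 2 in turn, with medians of -0.11 and -2.18 without young fresh 1 and young cultured 1 in turn). Members down numbered 3, 9 and 2 without young fresh 1 and 2 and young cultured 2 in turn, and those up 0 without young cultured 1. In all 16 of 32 lists shifted by camera with the preset correlation (8 up, 8 down), 1 with the estimated correlation, which was cholesterol synthesis, and 13 by fry. Fresh cells were not held for the same 26 hours, so time outside the body and the culture medium were not parted.

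In old stem cells 5825 of 18613 genes passed with culture by edgeR, 2806 up and 3019 down, and 1780 changed at least 2-fold. Of 3537 pseudogenes tested, 847 passed, and may share reads. Idi1 rose from 47.0 ± 1.25 to 596 ± 61.5 CPM (log2 fold 3.66 ± 0.09 (SE), edgeR adjusted p = 8.54e-09). The rises of Hmgcs1 (log2 fold 3.75, edgeR adjusted p = 8.54e-09), Msmo1 (3.64, adjusted p = 8.54e-09) and Cyp51 (3.29, adjusted p = 1.26e-08) were of the same pathway. Fdft1 (log2 fold 3.01, edgeR adjusted p = 1.38e-08), Acat2 (2.63, adjusted p = 8.54e-09) and Acat3 (2.81, adjusted p = 1.26e-08) rose, though the last 2 are near copies. Scd1 (log2 fold 3.13, edgeR adjusted p = 1.26e-08), Eno1 (2.20, adjusted p = 8.54e-09) and Eno1b (2.20, adjusted p = 8.54e-09) rose. Dusp6 fell from 67.2 ± 6.84 to 8.42 ± 0.273 CPM (log2 fold -3.00 ± 0.11 (SE), edgeR adjusted p = 5.69e-08), and Polg (log2 fold -1.82, adjusted p = 1.26e-06), Tfr2 (-1.47, adjusted p = 1.50e-06) and Camkk1 (-2.27, adjusted p = 2.73e-06) fell as in young cells. Also down were Tnfsf10 (log2 fold -1.74, edgeR adjusted p = 2.05e-06), which encodes the death ligand TRAIL, and Txnip (-1.89, adjusted p = 3.00e-06), which restrains glucose uptake. So were the lysosomal sulfatase gene Arsb (log2 fold -1.86, edgeR adjusted p = 3.16e-06) and the sterol exporter gene Abcg1 (-1.36, adjusted p = 3.28e-06). The interferon-induced GTPase genes Tgtp2 (log2 fold -1.76, edgeR adjusted p = 3.64e-06) and Irgm1 (-1.30, adjusted p = 3.98e-06) fell. Pbx1 did not pass (log2 fold 0.05 ± 0.11 (SE), edgeR adjusted p = 0.804).

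**Figure D3:**
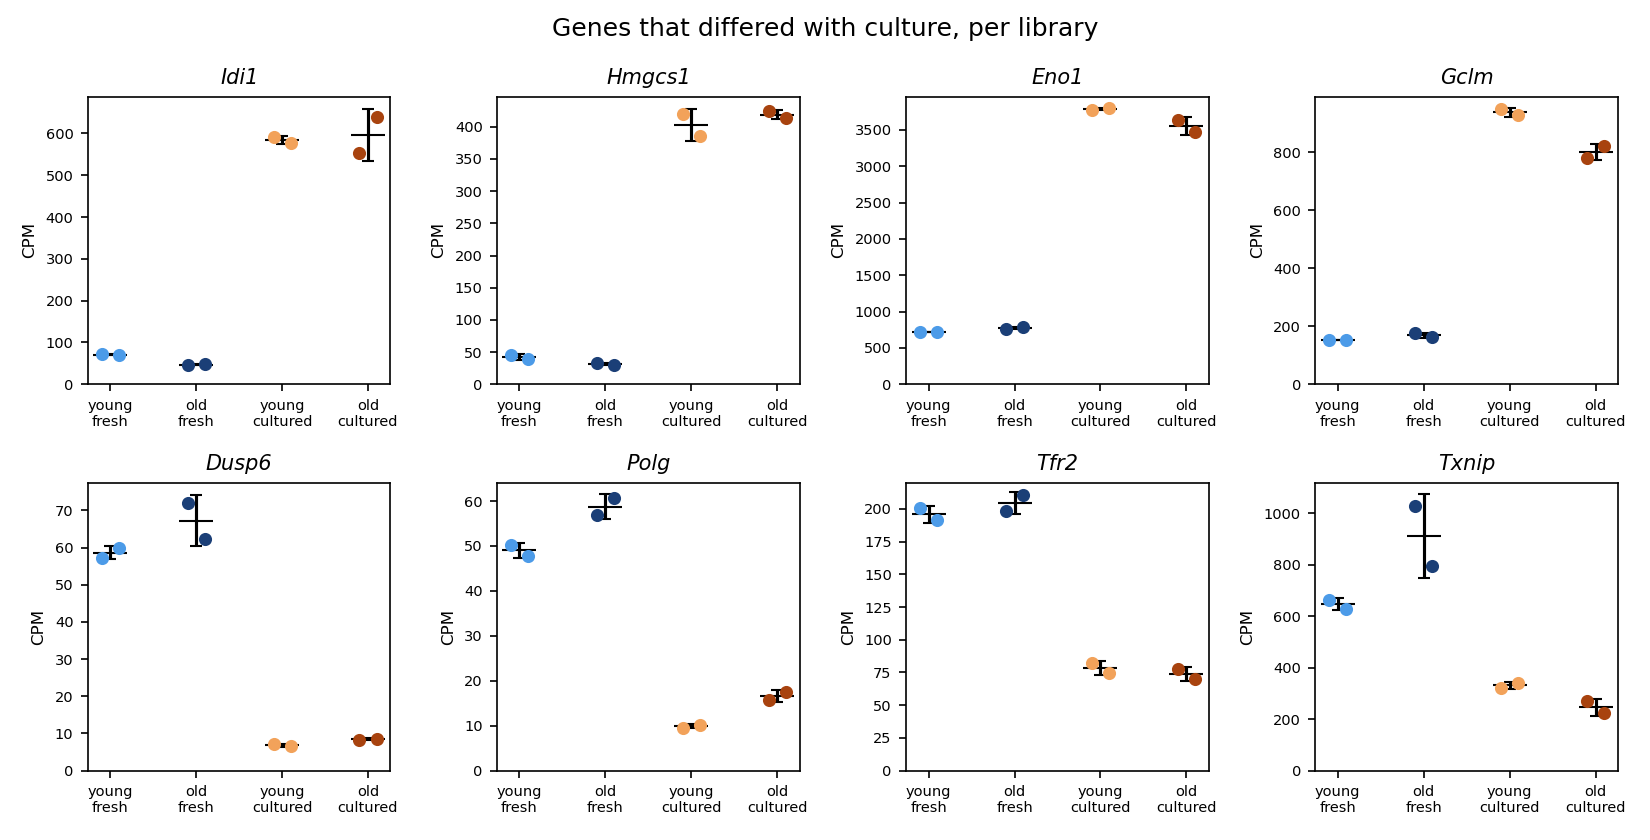
CPM of Idi1, Hmgcs1, Eno1, Gclm, Dusp6, Polg, Tfr2 and Txnip in the 4 groups, 1 point per library with the mean ± SD of 2 libraries. Idi1 averaged 70.8 CPM in fresh and 584 CPM in cultured young cells, and Dusp6 58.6 and 6.79 CPM.

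For cholesterol synthesis in old cells 24 of 24 genes passed as up and 0 as down (0 did not), 24 and 0 adjusted over the list alone. The median was 2.62 (camera adjusted p = 9.37e-31 and adjusted p = 0.00621 with an estimated correlation). For glycolysis 19 of 25 genes passed as up and 1 as down (5 did not), 20 and 1 adjusted over the list alone, with Aldoa (log2 fold 1.87, edgeR adjusted p = 4.21e-08) up. Median 1.07 was accompanied by camera adjusted p = 3.25e-16 and adjusted p = 0.122 with an estimated correlation. For hypoxia 16 of 32 genes passed as up and 0 as down (16 did not), 18 and 1 adjusted over the list alone, with Bnip3 (log2 fold 2.23, edgeR adjusted p = 5.66e-07) up. Its median of 0.84 came with camera adjusted p = 9.99e-08 and adjusted p = 0.256 with an estimated correlation. For the ATF4 amino acid response 26 of 34 genes passed as up and 2 as down (6 did not), 28 and 2 adjusted over the list alone, with Asns (log2 fold 1.50, edgeR adjusted p = 3.33e-06) up. The median was 0.67 (camera adjusted p = 8.38e-11 and adjusted p = 0.0806 with an estimated correlation). For p53 targets 14 of 27 genes passed as up and 4 as down (9 did not), 15 and 4 adjusted over the list alone, with Cdkn1a (log2 fold 3.81, edgeR adjusted p = 1.04e-06) and Bax (2.12, adjusted p = 1.11e-06) up and the kinase gene Plk2 (-2.39, adjusted p = 6.01e-05) down. Median 0.62 was accompanied by camera adjusted p = 0.000492 and adjusted p = 0.535 with an estimated correlation. Members down numbered 1 and 1 without old fresh 1 and old cultured 2 in turn. For megakaryocytes and platelets 13 of 28 genes passed as up and 2 as down (13 did not), 14 and 2 adjusted over the list alone, with Cd9 (log2 fold 1.36, edgeR adjusted p = 3.02e-06) up. Its median of 0.39 came with camera adjusted p = 0.000545 and adjusted p = 0.636 with an estimated correlation. Members of that list up numbered 8, 8, 8, 8 and 7 without young fresh 1 and 2, young cultured 1 and 2 and old cultured 2 in turn. The median became 0.60 and 0.16 without old cultured 1 and 2 in turn. For ribosome biogenesis 23 of 50 genes passed as up and 2 as down (25 did not), 25 and 2 adjusted over the list alone, with Npm1 (log2 fold 0.79, edgeR adjusted p = 2.56e-05) up. The median was 0.22 (camera adjusted p = 6.50e-05 and adjusted p = 0.636 with an estimated correlation). Members up numbered 13 and 11 without old fresh 1 and old cultured 2 in turn. The median became 0.12 without old cultured 2.

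For the interferon response in old cells 0 of 46 genes passed as up and 32 as down (14 did not), 1 and 34 adjusted over the list alone, with Stat1 (log2 fold -1.37, edgeR adjusted p = 2.27e-05) and Ifi47 (-0.85, adjusted p = 1.00e-05) down. Median -0.83 was accompanied by camera adjusted p = 1.49e-11 and adjusted p = 0.387 with an estimated correlation. For antigen presentation 1 of 24 genes passed as up and 21 as down (2 did not), 1 and 21 adjusted over the list alone, with H2-Aa (log2 fold -1.82, edgeR adjusted p = 8.62e-05) and Ciita (-2.24, adjusted p = 9.83e-05) down. Its median of -0.51 came with camera adjusted p = 1.81e-08 and adjusted p = 0.535 with an estimated correlation. Members down numbered 11 without old fresh 1. For the PBX, MEIS and HOX list 0 of 23 genes passed as up and 9 as down (14 did not), 0 and 9 adjusted over the list alone, with Hoxa9 (log2 fold -1.03, edgeR adjusted p = 0.000348) and Pbx2 (-0.74, adjusted p = 0.00210) down. The median was -0.56 (camera adjusted p = 0.00340 and adjusted p = 0.256 with an estimated correlation). Members down numbered 4 and 5 without old fresh 1 and old cultured 2 in turn. For stem cell surface genes 2 of 25 genes passed as up and 13 as down (10 did not), 2 and 16 adjusted over the list alone, with the receptor gene Tek (log2 fold -0.93, edgeR adjusted p = 0.000123) down. Median -0.49 was accompanied by camera adjusted p = 0.000127 and adjusted p = 0.535 with an estimated correlation. For stem cell transcription factors 4 of 33 genes passed as up and 13 as down (16 did not), 5 and 15 adjusted over the list alone, with Bmi1 (log2 fold -1.05, edgeR adjusted p = 0.000172) down and Runx1 (1.00, adjusted p = 1.88e-05) up. Its median of -0.38 came with camera adjusted p = 0.0209 and adjusted p = 0.574 with an estimated correlation. The transcription factor shift was lost (adjusted p = 0.0566 without old cultured 2), and the factors down numbered 7 without old fresh 1.

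For heat shock and unfolded protein genes 13 of 29 genes passed as up and 4 as down (12 did not), 14 and 4 adjusted over the list alone, with the secretory stress factor gene Xbp1 (log2 fold 1.39, edgeR adjusted p = 6.92e-07) up and the shift lost in 1 case (without old cultured 2). The median was 0.24 (camera adjusted p = 0.00953 and adjusted p = 0.636 with an estimated correlation). For lymphoid progenitors 0 of 17 genes passed as up and 7 as down (10 did not), 0 and 7 adjusted over the list alone, with Notch1 (log2 fold -1.40, edgeR adjusted p = 2.78e-05) down. Median -0.65 was accompanied by camera adjusted p = 0.0139 and adjusted p = 0.387 with an estimated correlation. For granulocytes and monocytes 1 of 26 genes passed as up and 6 as down (19 did not), 1 and 6 adjusted over the list alone, with Csf3r (log2 fold -1.36, edgeR adjusted p = 0.000366) down. Its median of -1.48 came with camera adjusted p = 0.00354 and adjusted p = 0.636 with an estimated correlation. The median became -0.92 without old fresh 1. The lists of DNA replication, mitosis, oxidative phosphorylation, lysosomes and the ribosome did not shift in old cells (camera adjusted p = 0.859, 0.602, 0.0682, 0.340 and 0.434), and the first 4 had medians of 0.00, 0.10, 0.10 and 0.14 that turned negative when only library size was used (-0.16, -0.06, -0.06 and -0.02). Mitosis shifted up without old cultured 1 (adjusted p = 0.0128, median 0.25), oxidative phosphorylation up without old fresh 2 (adjusted p = 0.00484) and the ribosome down without old cultured 1 (adjusted p = 0.0280). In all 15 of 32 lists shifted by camera with the preset correlation (8 up, 7 down), 1 with the estimated correlation, which was cholesterol synthesis, and 13 by fry. With all 8 libraries the aged stem cell list shifted with culture in neither age (camera adjusted p = 0.0799 in young and 0.115 in old cells), but in young cells it shifted up without young fresh 1 and young cultured 2 (adjusted p = 0.0317 and 0.0312, median 0.30 and 0.36), and in old cells down without old fresh 2 (adjusted p = 0.0119, median -0.59).

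**Figure D4:**
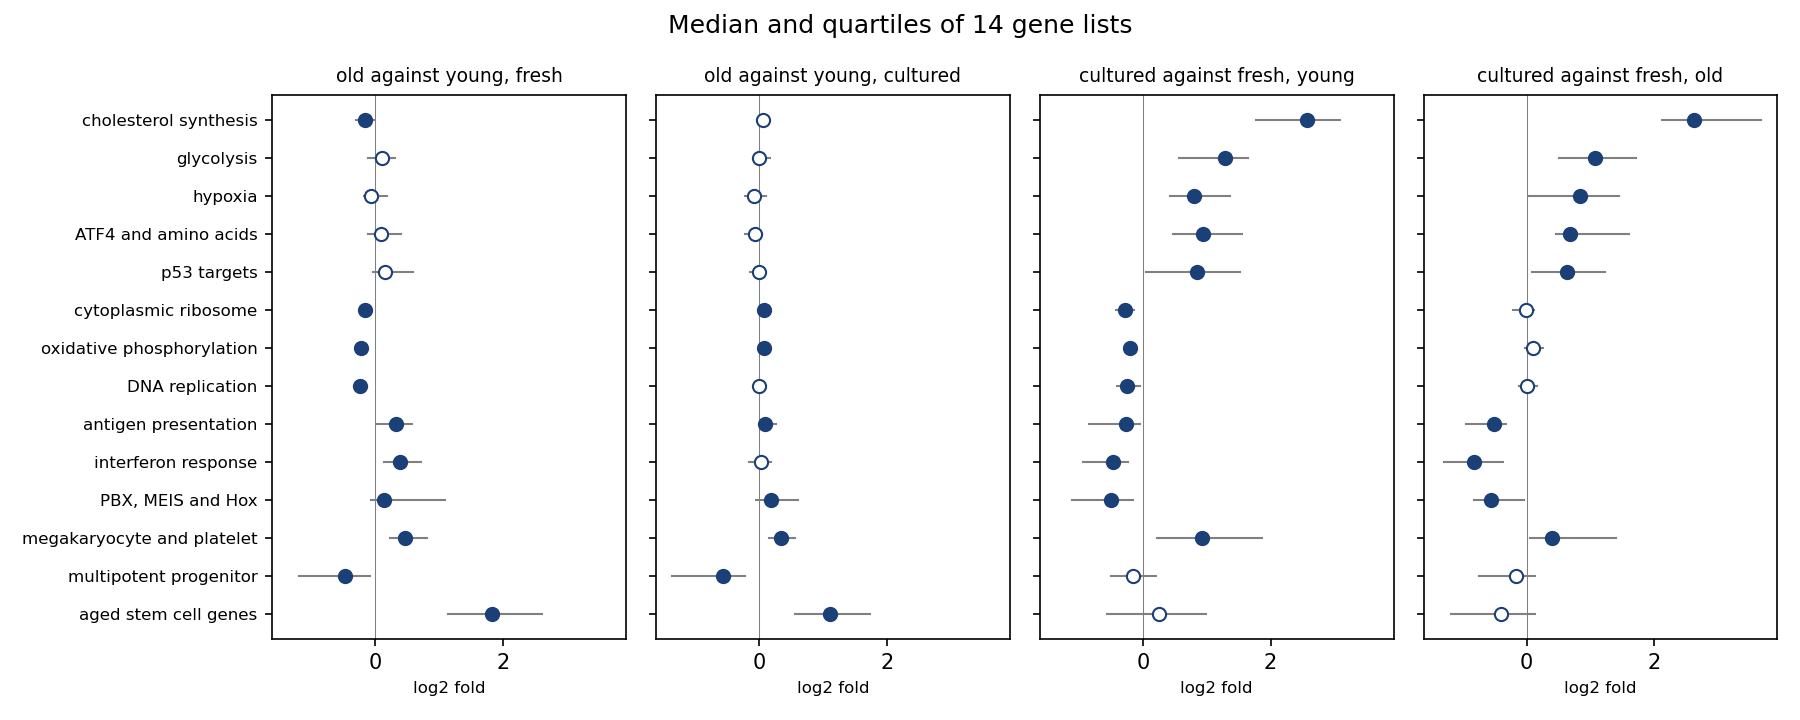
Median log2 fold of 14 gene lists in the 4 comparisons, with bars from the lower to the upper quartile of the members and filled points where the camera adjusted p was under 0.05 with the preset correlation. Cholesterol synthesis has medians of 2.57 and 2.62 with culture in young and old cells, and the aged stem cell list has 1.83 and 1.12 with age in fresh and cultured cells.

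The culture effects of young and old cells, which share no libraries, had 1872 genes up in both (468 expected if independent) and 1737 down in both (471 expected), and 39 passed in opposite directions by edgeR. Over the 18613 genes tested, the log2 folds of culture correlated with r = 0.724 (Pearson) and 0.661 (Spearman).

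The difference between the culture effects of old and young cells was tested gene by gene and list by list. By edgeR 0 of 18613 genes passed, with 3143 at an unadjusted p under 0.05, and limma-voom called 0 while DESeq2 called 850. With other settings edgeR called 1143 (no filter on low counts), 233 (at least 5 CPM in 2 libraries), 202 (a replicate block of age and number) and 6 (protein coding symbols only). The edgeR count was 22, 1, 10 and 12 without young fresh 1, old fresh 1, old fresh 2 and old cultured 1 in turn.

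The smallest p values are given as values, and the 10 genes named next passed by DESeq2 and with the first 3 of those edgeR settings. The adhesion scaffold gene Tns1 had the smallest adjusted p (log2 fold -1.03 ± 0.11 (SE), edgeR adjusted p = 0.0674). Values below 0 followed for the actin genes Fhdc1 (log2 fold -1.60, edgeR adjusted p = 0.0740) and Afap1l1 (-0.82, adjusted p = 0.0740). The TGF-beta coreceptor gene Tgfbr3 (log2 fold -0.75, edgeR adjusted p = 0.0740) and the RNA decay gene Smg6 (-0.82, adjusted p = 0.0740) lay below 0 too. Values above 0 followed for the RNA binding gene Raly (log2 fold 1.12, edgeR adjusted p = 0.0740), the signaling regulator gene Rgs1 (0.84, adjusted p = 0.0740) and Idi1 (0.62, adjusted p = 0.0740). The cyclophilin gene Ppia (log2 fold 0.48, edgeR adjusted p = 0.0740) and its near copy Gm10123 (0.49, adjusted p = 0.0740) lay above 0 too. Pbx1 had a difference of 0.18 ± 0.16 (SE), edgeR adjusted p = 0.617. On the aged stem cell list Plscr2 (log2 fold -0.98, edgeR adjusted p = 0.0740) and Vwf (-0.94, adjusted p = 0.0792) lay below 0.

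Of 32 lists 13 shifted by limma camera with the preset correlation (5 up, 8 down), 0 with the estimated correlation (adjusted p = 0.304 to 0.632) and 0 by fry, and no member of them passed over all genes. On the aged stem cell list 40 of 48 genes lay below 0, 20 of them passing when adjusted over the list alone (median -0.56, camera adjusted p = 4.49e-10). On the oxidative phosphorylation list 57 of 60 lay above 0, with 26 passing over the list alone (median 0.34, camera adjusted p = 8.94e-17), such as the oxidase gene Cox7b (log2 fold 0.70, edgeR adjusted p = 0.0763). On the ribosome list 73 of 74 lay above 0 and 0 passed over the list alone (median 0.23, camera adjusted p = 3.39e-14). The median became 0.15 without young fresh 1. DNA replication had 39 of 44 genes above 0 (median 0.27, camera adjusted p = 1.74e-07). The median became 0.17 without old fresh 1. Cholesterol synthesis had 7 of 24 higher over the list alone (median 0.26, camera adjusted p = 0.000101), with Mvd (log2 fold 1.10, edgeR adjusted p = 0.0792) above 0.

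The interferon response had 13 lower and 1 higher of 46 over the list alone (median -0.34, camera adjusted p = 3.53e-05), with Rsad2 (log2 fold -1.12, edgeR adjusted p = 0.0740) below 0. The median became -0.21 and -0.18 without young cultured 2 and old cultured 2 in turn. Stem cell surface genes lay lower (median -0.33, camera adjusted p = 6.29e-05). The median became -0.14 without old cultured 2. Lysosome genes lay lower too (median -0.25, camera adjusted p = 0.000177). The median became -0.15 without old cultured 2. The remaining 5 shifts were lost when single libraries were left out. Antigen presentation (median -0.22, camera adjusted p = 0.00847) had adjusted p = 0.596 without old cultured 2 (median -0.36 to -0.04 with 1 library left out). The p53 targets (median -0.23, camera adjusted p = 0.0193) had adjusted p = 0.0701, 0.125, 0.0518 and 0.335 without young fresh 1, young cultured 1, old fresh 2 and old cultured 1 in turn (median -0.47 to -0.10 with 1 library left out). Mitosis (median 0.29, camera adjusted p = 1.41e-05) had adjusted p = 0.0626 without old cultured 2 (median 0.09 to 0.45 with 1 library left out). Stem cell transcription factors (median -0.19, camera adjusted p = 0.00739) had adjusted p = 0.0650 without old cultured 2 (median -0.31 to -0.10 with 1 library left out). Megakaryocyte genes (median -0.25, camera adjusted p = 0.00739) had adjusted p = 0.125, 0.115 and 0.533 without young cultured 1, old fresh 2 and old cultured 1 in turn (median -0.44 to -0.05 with 1 library left out), and their median was -0.05 without the 5 genes shared with the aged list.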

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

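The length and GC test (its bounds set before its result), the tests of B cell markers, of regression among the aged stem cell list's members and of uniform shrinkage, and the bootstrap interval for macrophage and dendritic cell markers were chosen or reworded after the data were seen, and the other tests were set before their results.

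Culture effects differed between old and young cells for 13 lists by limma camera on the difference itself. Medians of old minus young were -0.56 for the aged stem cell list (adjusted p = 4.49e-10), -0.19 for stem cell transcription factors (0.00739), -0.33 for stem cell surface genes (6.29e-05), 0.27 for DNA replication (1.74e-07), 0.29 for mitosis (1.41e-05) and 0.34 for oxidative phosphorylation (8.94e-17). They were 0.26 for cholesterol synthesis (adjusted p = 0.000101), -0.23 for p53 targets (0.0193), -0.34 for the interferon response (3.53e-05), -0.22 for antigen presentation (0.00847), -0.25 for lysosomes (0.000177), 0.23 for the ribosome (3.39e-14) and -0.25 for megakaryocytes (0.00739; -0.05 without 5 genes shared with the aged list). With an estimated correlation camera gave adjusted p = 0.304 to 0.632 for them, so weakly correlated genes are assumed, and fry called 0 lists. Without single libraries the calls of antigen presentation, p53 targets, megakaryocytes, mitosis and transcription factors were lost (highest adjusted p = 0.596, 0.335, 0.533, 0.0626 and 0.0650).

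The aged stem cell list had a median age fold of 1.83 in fresh and 1.12 in cultured cells, a ratio of 0.612 (95% bootstrap interval over genes 0.512 to 0.724). With 1 of the 8 libraries left out the median difference was -0.78 to -0.38. Of all 389 genes called in cultured cells 36.0% had the larger fold in fresh cells, which says nothing on regression toward the mean, since picking by that call favors the larger fold in cultured cells. Among the list's called members, picked the same way, 28 of 31 (90.3%, exact 95% interval 74.2 to 98.0) had the larger fold in fresh cells. The progenitor list had a ratio of 1.20 (0.658 to 2.55), and the ratio difference an interval of 0.0362 to 1.90. Intervals over genes omit library error, so uniform shrinkage stays open. Culture may narrow this part of the age difference, but the list was written from knowledge of fresh aged cells, which these tests leave open.

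The oxidative phosphorylation list lay lower in old fresh cells (median log2 difference -0.24), with 8 of 60 genes passing by edgeR, 0 without old fresh 1, and camera adjusted p = 0.326 with an estimated correlation. After correction of each library for transcript length and GC content the median was -0.18 (95% bootstrap interval -0.22 to -0.16), and with each fresh library left out it was at most -0.16. The medians stayed negative, but the interval omits library error. Differences of pools or libraries, with or without age, stay open.

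Class II genes were higher in old fresh cells (median log2 fold 1.87 over 7 genes, 5 of them called by edgeR), with at least 1.78 whichever fresh library was left out. Mature B cells, which the lineage gate should remove, would raise their abundant transcripts, but the largest rise among Cd79a, Cd79b, Cd19, Ms4a1 and Ighm was 0.109 CPM, against at least 225 CPM for Cd74. A first form of this test asked that none of the 5 reach 5 CPM, and Cd79b stood at 32.5 and 32.8 CPM in old and at 32.9 and 39.3 CPM in young fresh cells. For macrophages and dendritic cells, which the gate should remove too, 11 of 16 markers were tested and had a median log2 fold of 0.52 (0.11 to 1.77), between the bounds set for and against them, so this source stays open. C1qa, C1qb and C1qc stood at 0.201 to 1.25 CPM in young and 0.880 to 3.33 CPM in old fresh libraries, and Lyz2 had a log2 fold of -0.23.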

How the results depend on the processing

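The fit of protein coding symbols only and the length and GC correction were chosen after the data were seen, the other settings before.

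Genes changed numbered 1216 to 1797 for age in fresh cells with DESeq2 size factors, library size only, at least 5 CPM in 2 libraries, DESeq2, limma-voom, the 4 libraries alone, a spread that was not robust, a replicate block (1264), protein coding symbols only and the normalized table. With no filter on low counts they were 2610, 1215 and 1143 for age in fresh cells, age in cultured cells and the difference between culture effects. With a log2 fold of at least 1, a stricter line on the same fit, they were 497, 195, 1784 and 1780 for the 2 age and the 2 culture effects. DESeq2 gave 726 for age in cultured cells and 850 for the difference between culture effects. That difference also had 233 genes with at least 5 CPM in 2 libraries, 202 with a replicate block of age and number and 6 with protein coding symbols only, against 0 with a replicate block of number alone, and the cause was not tested. Other settings gave 352 to 504 for age in cultured cells, 4601 to 7370 for culture in young cells and 4513 to 6696 for culture in old cells.

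Shared genes of the 2 age effects numbered 612 with no filter, 360 by DESeq2 and 147 with a log2 fold of at least 1, and those of the 2 culture effects 1028 with a log2 fold of at least 1. The cause of the first 2 was not tested. A replicate block gave 413 genes for age in cultured cells, 5954 and 5756 for culture in young and old cells, and 245 and 3563 shared genes. The labels do not tie the numbers to pools, and the numbers explained little (r of the deviations -0.04 to 0.13).

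Lists shifted numbered 0, 0, 1, 1 and 0 for age in fresh cells, age in cultured cells, culture in young cells, culture in old cells and the difference, with camera and an estimated correlation. By fry they were 5, 2 and 0 for the 2 age effects and the difference, and 13 for each culture effect. Both methods let the genes of a list be correlated. DESeq2 size factors, a replicate block, protein coding symbols only and the length and GC correction gave 11 to 17, 11 to 12, 14 to 16, 15 to 16 and 11 to 14.

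With each library left out in turn, genes changed ranged from 369 to 1547, 39 to 429, 3564 to 6198, 3893 to 5633 and 0 to 22 for the 5 comparisons in that order. Shared genes ranged from 30 to 231 for age and from 2489 to 3272 for culture. Lists shifted ranged from 14 to 18, 11 to 13, 16 to 18, 13 to 17 and 11 to 17. The cause was not tested.

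Single genes were followed over every member the naming rule allows, printed or not, since printed members were picked partly for keeping their call. Calls were lost without 1 library for 16 of 61 genes for age in fresh cells and 23 of 43 for age in cultured cells, and for 0 of 56 and 0 of 58 for culture in young and old cells. Other settings ended 4 and 3 of the age calls, 1 and 1 of them with protein coding symbols only. No called gene changed direction under the settings tried. The log2 fold of Pbx1 with culture, not called, turned from -0.13 in young cells to 0.0047 without young cultured 2 (range with libraries left out -0.28 to 0.0047). In old cells it turned from 0.05 to -0.11 with library size only and to -0.069 without old cultured 2 (range -0.07 to 0.15).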

Other observations

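The 5 lists given here were chosen after the results were seen, and no explanation is offered for them.

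Their camera p values use an estimated correlation and are adjusted over these and the 32 other lists together. Histone genes gave 12 of 20 lower in old than in young fresh cells by edgeR (median log2 fold -0.78, camera adjusted p = 0.330), H1f5 among them (log2 fold -1.34, edgeR adjusted p = 0.00358). In culture 14 fell in young cells (median -1.32) and 13 fell and 2 rose in old cells (median -0.74, camera adjusted p = 0.499 and 0.657). NRF2 targets rose with culture, 17 of 22 in young and 18 of 22 in old cells (medians 1.23 and 0.97, camera adjusted p = 0.0716 and 0.0802). Fatty acid synthesis genes rose in 17 of 18 cases in each age (medians 1.51 and 1.24, camera adjusted p = 0.0249 and 0.0282). Genes of interferon-gamma induced GTPases were higher in old fresh cells in 10 of 17 cases (median 0.77, camera adjusted p = 0.330), and 14 and 16 fell with culture (medians -1.07 and -1.62, camera adjusted p = 0.450 and 0.281). Of 19 imprinted genes, 3 were higher and 1 lower with age in fresh cells, 0 and 2 in cultured cells, and with culture 6 rose in young cells and 3 rose and 3 fell in old cells.

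Some markers of other cells rose in culture. Pf4 stood at 96.0 to 276 CPM fresh and 354 to 1005 CPM cultured, and Ppbp at 4.62 to 9.79 and 46.5 to 227. Hbb-bs stood at 7.50 to 57.3 and 301 to 411. Hba-a1 (1.865 to 63.5, 0.545 to 1.13) and Lyz2 (261 to 338, 206 to 247) fell. Mpo stood at 72.0 CPM in young fresh 1 and 0.453 to 28.6 CPM elsewhere, and Cd3e at 0 to 0.106 CPM.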
